A study of Mus musculus with 12 samples.

How the data were processed

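RNA sequencing of CT26 cells, a mouse colon carcinoma line, was analysed for 12 libraries in 4 groups of 3, from cells treated for 24 h with PBS, NP@M, NP-D@M or NP-D@MP. The labels do not explain these abbreviations; the series title describes a nanodrug coated with engineered cancer cell membrane that is directed at CDKs and given with PD-L1 antibody therapy. The groups and replicates were taken from the sample titles, which number the libraries in a single series, so no library number was shared between groups and no paired fit was made. Per the labels' protocols, libraries were made from 1 ug of total RNA with an Illumina TruSeq kit. The same protocol text speaks of retinas, in conflict with the cell line named in the labels, so genes of the retina were looked up among the markers of other cell types. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

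The authors deposited a single table of FPKM values for 12584 genes with identifiers, coordinates and lengths; neither the gene counter, nor the strand setting, nor the rule that chose these genes is given in the sources used here. Bowtie 0.12.2 and the mm8 build are named per the submitters' processing notes. The identifiers and coordinates in the table were instead those of GRCm38: 12580 of the 12584 identifiers were found in the GENCODE M21 annotation of that build, all of these on the same chromosome and 12113 with identical coordinates. Coordinates are therefore given for GRCm38 as the table holds them.

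The product of FPKM and gene length was, for 100% of the values in every library, a whole multiple of a single step per library within a relative tolerance of 1e-06, so whole reads and the library size by which the authors had divided were recovered. The reads in the table summed to between 12.8 and 15.7 M reads (mega-reads) per library. The recovered library size, called the effective library size here, was 28.2 to 31.1 M reads in the libraries without D in their name and 7.13 to 8.4 M reads in those with it. It was thus 1.95 to 2.02 times the reads in the table in the former and 0.533 to 0.565 times in the latter; how the authors obtained it is not given in the sources used here. A read in a gene of 1 kb was worth 0.0322 to 0.0355 FPKM in the former libraries and 0.119 to 0.140 FPKM in the latter. The floor used for a gene at 0 in a whole group was 3 reads per library, and it covers counting error only. Folds against it are bounds in the authors' scaling. Replicate libraries of a group differed by more than sampling noise (chi-square per degree of freedom from 7.10 to 62.6 between pairs), so none was treated as a duplicate.

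The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a filter of at least 1 FPKM in at least 3 libraries, which left 10101 genes, and with all 12 libraries in a single fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, while folds are ratios of mean FPKM. Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 25 of 32 lists with at least 5 tested members. The design, the lists, the rule for named genes and the alternative settings were fixed before the data were examined. By that rule the text names, for each comparison, genes from the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, with a mean of at least 5 FPKM in the higher group and a symbol that is not a predicted locus; the 2 called members with the smallest p in the direction of each called list; and 13 genes fixed by name. The rule, written before the data were examined, fixed another gene by name as well, which was left out on request and not because of its values.

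Alternative settings fixed then were scaling to a common median ratio, quantile normalization, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, limma with trend and robust settings, a fit on only the 6 libraries compared, a log2 change of at least 1, an adjusted p under 0.01, leaving out each library, an estimated inter-gene correlation and rank-based camera. Chosen after seeing the data were scaling to the reads in the table, limma voom on the recovered reads with the effective library sizes, removal of a smooth trend on GC content, and removal of a trend on gene length before the list test. On data simulated with 200 changed genes and a dispersion of 0.01, which was not fitted to the spread between these libraries, the steps called, for NP-D@MP vs NP-D@M with 10087 genes tested, 58.2% of the genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, and 13.1% of the calls were false. For NP@M vs PBS with 10085 genes tested, these shares were 66.7%, 97.0% and 100%, with 3.35% of the calls false. Overlapping genes and the share of words of 50 bases also found in transcripts of other genes were read from GENCODE M21 for the named genes. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.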

Results

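Gene expression was measured by RNA sequencing in CT26 mouse colon carcinoma cells treated for 24 h, in 4 groups of 3 libraries, and 10101 genes were tested. The reads in the table were 15.1 ± 1.01 M (mega-reads, mean ± SD, n = 3) for PBS and 15.3 ± 0.201 M for NP@M. They were 14.2 ± 1.21 M for NP-D@M and 13.9 ± 0.435 M for NP-D@MP. The effective library size behind the FPKM values was 29.8 ± 1.45 M for PBS and 30.5 ± 0.748 M for NP@M, against 7.95 ± 0.612 M for NP-D@M and 7.40 ± 0.236 M for NP-D@MP. Mitochondrial genes held 3.35 ± 0.0486% of the reads with PBS and 4.0 ± 0.22% with NP@M, against 12.2 ± 2.79% with NP-D@M and 8.94 ± 1.43% with NP-D@MP. Ribosomal protein genes held 6.09 ± 0.359% with PBS and 5.86 ± 0.275% with NP@M, against 13.8 ± 1.16% with NP-D@M and 14.7 ± 0.279% with NP-D@MP. The noncoding RNA Gm26917, singled out after its values were seen, held 0.0112 ± 0.000785% of the reads with PBS and 0.00742 ± 0.00146% with NP@M. It held 1.59 ± 0.528% with NP-D@M and 1.97 ± 0.373% with NP-D@MP. Across genes, which are not independent replicates, pairs of libraries without D correlated at r from 0.981 to 0.994 and pairs with D at r from 0.975 to 0.992. Where only 1 library of the pair had D, r was 0.768 to 0.802.

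**Figure D1:**
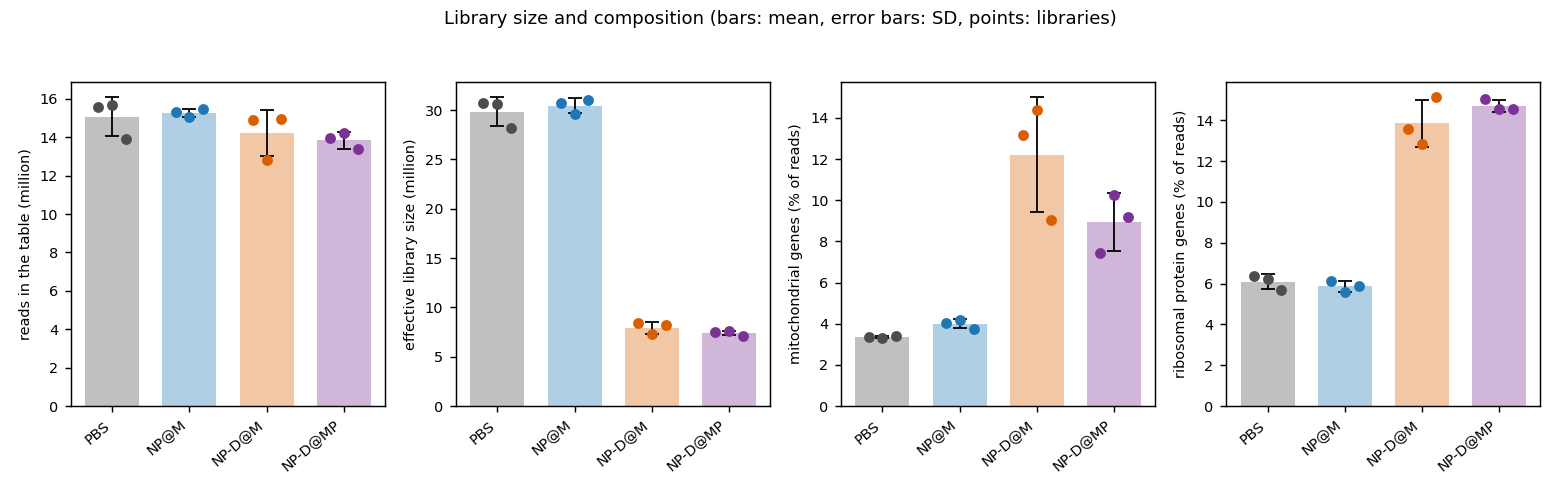
Reads in the table (M reads), effective library size (M reads), and the shares of reads in mitochondrial and ribosomal protein genes (%) for the 12 libraries, with bars at the mean, error bars at the SD and points for libraries. The reads in the table lay between 12.8 and 15.7 M in all 4 groups, while the effective library size lay between 28.2 and 31.1 M without D and between 7.13 and 8.4 M with D.

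Because the effective library sizes differed in this way, the level of a gene with D depended on the scaling. Scaled to the reads in the table, the median log2 change of all genes moved by -1.24 in NP-D@M vs NP@M, by -1.25 in NP-D@M vs PBS and by -1.27 in NP-D@MP vs PBS. Some genes named below moved further. In NP-D@M vs NP@M the log2 change of Ctsb went from 3.36 to 1.54 and that of Calr from 3.56 to 1.73. Cdk5 went from 3.15 to 1.42 and Cdk1 from -2.84 to -4.21. Medians of gene lists are therefore given relative to the median of all tested genes, and directions that turn under another scaling are named with the result. How the authors' library sizes were obtained is not given, and the other scalings are relative within a library. A rise or fall here thus does not show whether RNA per cell changed.

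The comparison of NP@M with PBS sets the treatment labelled NP@M against PBS. None of the 13 genes fixed by name was called. Cdk1, the kinase gene of entry into mitosis, stood at 17.3 ± 1.25 FPKM with NP@M and 17.6 ± 0.582 with PBS (n = 3, limma Benjamini-Hochberg adjusted p = 0.957). Cd274, which encodes PD-L1, stood at 1.02 ± 0.358 and 1.03 ± 0.0397 FPKM (limma adjusted p = 0.974). The only call was a fall of the predicted small nucleolar RNA Gm24837 (ENSMUSG00000089308, chromosome 4, 41211502 to 41211582, GRCm38), named after its values were seen. It went from 1.93 ± 0.149 FPKM to 0, with 5, 5 and 4 reads against 0 in each of the 3 NP@M libraries (limma adjusted p = 2.64e-06). It lies within Ubap2, and limma voom on the recovered reads gave it an adjusted p of 0.0595. Short-lived and immediate early transcripts stood lower than other genes by a median of -0.23 (camera adjusted p = 0.000527, and adjusted p = 0.645 with an estimated correlation), with 0 of 32 members called over all genes and 1 lower when adjusted over the list alone. Ribosomal proteins stood lower by a median of -0.10 (camera adjusted p = 0.00936, and adjusted p = 0.645 with an estimated correlation), with 0 of 39 members called over all genes or adjusted over the list alone. The call of ribosomal proteins also ended without PBS replicate 1, PBS replicate 2 or NP@M replicate 2 (adjusted p up to 0.123) and with a trend on gene length removed (adjusted p = 0.155). Neither list was tested with a GC trend removed. Median log2 changes ran from 0.21 in the 10% of genes lowest in GC content to -0.21 in the 10% highest. In all, limma called 0 genes higher and 1 lower, 1092 genes had an unadjusted p under 0.05, and limma voom called 0. Without PBS replicate 3 or NP@M replicate 2, limma called 2 genes. In 2870 genes (28.4%) the groups did not overlap. Barring ties, the mean of this share over the 10 splits of 6 libraries is 10%. All genes share the libraries, so a single split can lie above 10% without an effect of the treatment.

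The comparison of NP-D@M with NP@M sets a treatment with D in its name against its counterpart without it. Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938, GRCm38) fell from 17.3 ± 1.25 to 1.59 ± 0.515 FPKM, 10.9-fold lower (n = 3 per group, log2 change -2.84, SE 0.139, limma Benjamini-Hochberg adjusted p = 3.32e-09). Cdk2 (ENSMUSG00000025358, chromosome 10, 128697939 to 128705031), a kinase gene of entry into S phase, fell from 4.56 ± 0.336 to 1.47 ± 0.126 FPKM. Cdk9 (ENSMUSG00000009555, chromosome 2, 32705784 to 32713076), the kinase gene of transcription elongation, fell from 7.58 ± 0.423 to 4.17 ± 0.298 FPKM. Cdk5 (ENSMUSG00000028969, chromosome 5, 24418241 to 24423530) rose from 7.09 ± 0.849 to 71.1 ± 10.4 FPKM. Mcl1 (ENSMUSG00000038612, chromosome 3, 95658788 to 95663176), an anti-apoptotic gene, fell from 62.2 ± 3.73 to 9.79 ± 3.31 FPKM. The transcription factor gene Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374) fell from 27.8 ± 1.32 to 15.2 ± 2.90 FPKM. Cdkn1a, which encodes the CDK inhibitor p21, fell from 38.4 ± 4.15 to 9.41 ± 0.685 FPKM, and Mdm2, the ubiquitin ligase gene of p53, from 22.9 ± 1.43 to 16.1 ± 1.24 FPKM. For each of these 8 genes all 3 libraries of a group lay on the same side of the 3 of the other, and the highest adjusted p among them was 0.000721, for Mdm2.

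Among genes of immune recognition, Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095, GRCm38) fell from 1.02 ± 0.358 to 0.112 ± 0.194 FPKM (n = 3, log2 change -0.86, SE 0.159, limma adjusted p = 0.0003). The NP-D@M libraries had 0, 0 and 10 of its reads, and with quantile normalization its adjusted p was 0.0547. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), the light chain gene of MHC class I, rose from 663 ± 49.0 to 5859 ± 533 FPKM, a log2 change of 3.14 that turned to -0.15 with quantile normalization. The heavy chain gene H2-K1 rose from 15.8 ± 1.68 to 152 ± 59.2 FPKM. The chemokine genes Ccl5 and Cxcl10 rose from 0.125 ± 0.135 to 3.35 ± 1.72 FPKM and from 0.174 ± 0.0347 to 3.74 ± 0.421 FPKM. Ccl5 had 0, 3 and 8 reads with NP@M and 43, 17 and 18 with NP-D@M. Cxcl10 had 13, 9 and 14 reads with NP@M and 65, 69 and 66 with NP-D@M. Scaled to the reads in the table, the log2 change went from 1.89 to 1.15 for Ccl5 and from 2.01 to 1.17 for Cxcl10. Without NP@M replicate 3 the NP@M mean of Ccl5 was 0.0527 FPKM.

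Of the 8 largest rises that the naming rule picked, 6 were small noncoding RNAs. Whether the capture of such RNAs in the libraries differed with D was not tested. Of all 26 tested small nucleolar RNAs, counted after their values were seen, 10 rose and 7 fell, which turned to 7 and 9 scaled to the reads in the table. The small nucleolar RNA Snora17 (ENSMUSG00000077192, chromosome 2, 26639190 to 26639321, GRCm38) rose from 2.59 ± 1.43 to 2203 ± 466 FPKM (n = 3, log2 change 9.32, SE 0.303, limma adjusted p = 1.61e-10). The spliceosomal RNAs Rnu1a1 and Rnu5g rose from 0.918 ± 1.26 to 370 ± 104 FPKM and from 0.559 ± 0.732 to 191 ± 66.3 FPKM, and Rnu12 rose from 0.853 ± 1.48 to 303 ± 89.8 FPKM. Without NP@M replicate 3 the NP@M means of these genes were 0.199, 0.146 and 0 FPKM. Snord118 and Rnu2-10 had 0 reads in the 3 NP@M libraries and 81.7 ± 13.7 and 67.5 ± 49.4 FPKM with NP-D@M. In the authors' scaling these were at least 112-fold and at least 131-fold higher than a floor of 3 reads per library. The NP-D@M libraries had 80, 95 and 86 reads of Snord118 and 28, 161 and 108 of Rnu2-10. The respiratory chain gene Uqcr11 rose from 8.83 ± 2.25 to 423 ± 300 FPKM and the phosphatase inhibitor gene Ppp1r14b from 66.3 ± 3.54 to 2355 ± 746 FPKM. The NP-D@M mean of Uqcr11 was 252 FPKM without NP-D@M replicate 3, and that of Rnu2-10 was 43.2 FPKM without NP-D@M replicate 2. Other genes hold part of the 50-base words of Rnu1a1 (100%), Rnu2-10 (100%), Rnu5g (82.1%), Rnu12 (53.9%), Ppp1r14b (37.6%) and Snord118 (17.4%), so their levels are uncertain.

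Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032, GRCm38), a pseudokinase gene among the falls that the rule picked, fell from 53.3 ± 5.91 to 1.70 ± 0.483 FPKM (n = 3, log2 change -4.34, SE 0.149, limma adjusted p = 2.16e-10). Herpud1, a gene of protein degradation at the endoplasmic reticulum, fell from 43.7 ± 0.422 to 1.43 ± 0.663 FPKM. The immediate early gene Fosb fell from 25.1 ± 3.44 to 0.646 ± 0.159 FPKM and Akirin2 from 33.0 ± 3.52 to 1.18 ± 1.03 FPKM, with an NP-D@M mean of 0.601 FPKM without NP-D@M replicate 2. Myadm fell from 60.01 ± 2.53 to 1.91 ± 0.705 FPKM and Steap1 from 114 ± 4.92 to 6.77 ± 0.345 FPKM. The importin gene Kpna2 stood at 44.1 ± 0.909 FPKM with NP@M and is listed with 0, 0 and 4 reads with NP-D@M. Its level is uncertain, since 92.4% of its 50-base words occur in other genes. Snord72, which lies within Rpl37, had 0 reads in the 3 NP-D@M libraries against 20.6 ± 5.63 FPKM, at least 4.40-fold lower than with NP@M.

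**Figure D2:**
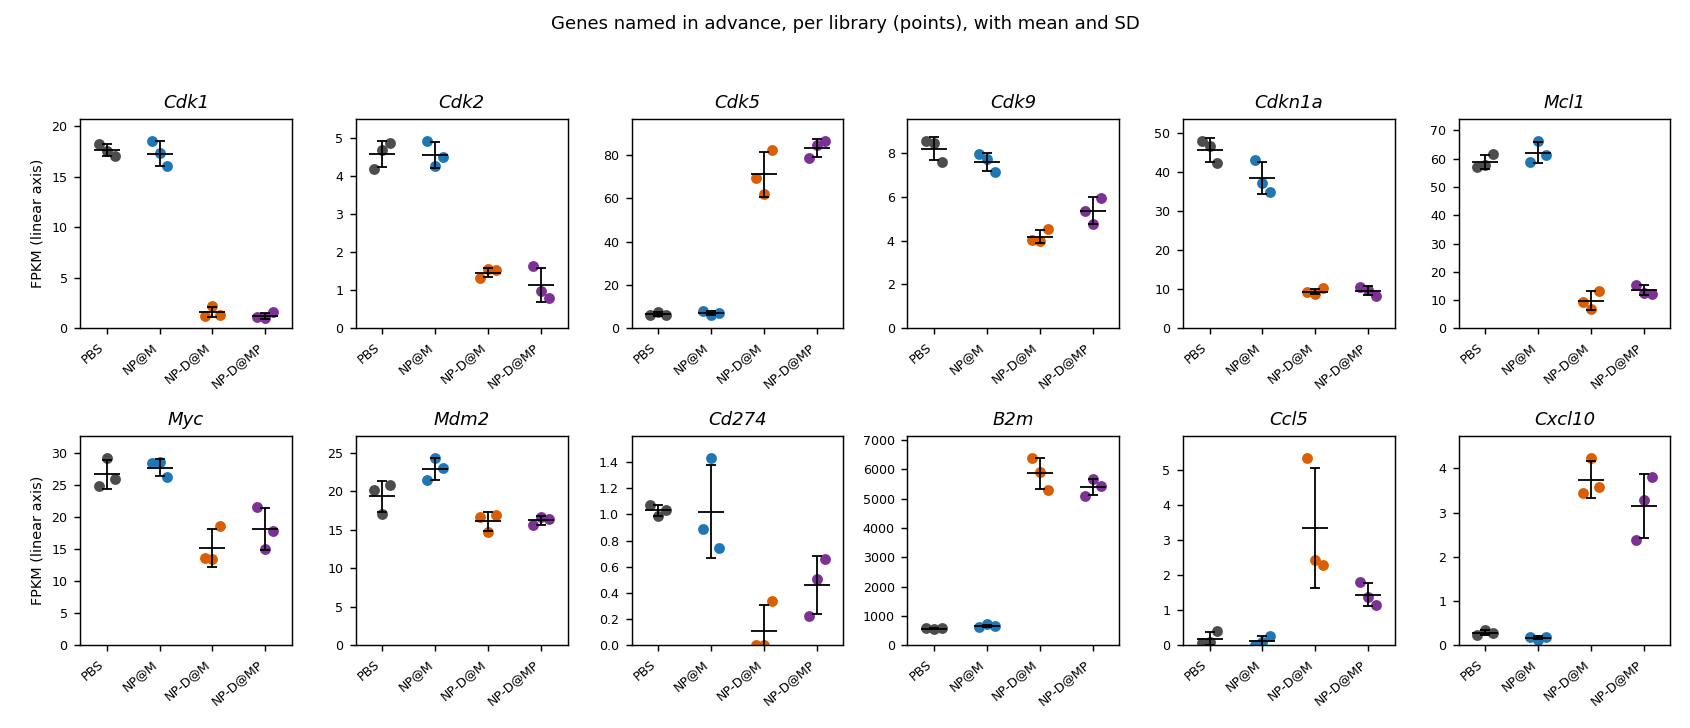
FPKM, on linear axes in the authors' scaling, of 12 of the 13 genes fixed by name in the 4 groups, with points for libraries, a bar at the mean and error bars at the SD (n = 3). Cdk1 lay at 17.6 and 17.3 FPKM without D and at 1.59 and 1.23 FPKM with D, while the rise of B2m in NP-D@M vs NP@M and in NP-D@MP vs PBS turned with quantile normalization.

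Ribosomal proteins stood highest among the lists in NP-D@M vs NP@M: 39 of 39 rose (39 adjusted over the list alone), with 36 higher and 1 lower when scaled to the reads in the table but 13 higher and 14 lower with quantile normalization. Their median lay 3.05 above that of all genes (camera adjusted p = 1.74e-12, and adjusted p = 0.212 with an estimated correlation). Rplp0 (ENSMUSG00000067274, chromosome 5, 115559467 to 115563727, GRCm38) rose from 719 ± 54.1 to 10673 ± 433 FPKM (n = 3), with 41.8% of its 50-base words in other genes, and Rps24 rose from 84.0 ± 2.57 to 755 ± 64.3 FPKM. Of 28 genes of lysosome and autophagy, 21 rose and 4 fell (21 and 4 adjusted over the list alone, 15 and 11 scaled to the reads in the table). Their camera adjusted p was 0.000144, and adjusted p = 0.198 with an estimated correlation. Among them, the cathepsin gene Ctsb rose from 64.0 ± 1.04 to 665 ± 3.10 FPKM and the saposin precursor gene Psap from 118 ± 4.45 to 1224 ± 56.3 FPKM. Of 19 genes of MHC class I antigen presentation, 16 rose and 3 fell (16 and 3 adjusted over the list alone, 10 and 5 scaled to the reads in the table). Camera gave them an adjusted p of 0.00128, and adjusted p = 0.198 with an estimated correlation. The chaperone gene Calr (ENSMUSG00000003814, chromosome 8, 84841850 to 84846934) rose from 110 ± 2.90 to 1300 ± 53.9 FPKM and the proteasome activator gene Psme1 from 21.03 ± 1.04 to 204 ± 10.1 FPKM. Of 16 replication-dependent histone genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone, 9 and 2 scaled to the reads in the table). Their camera adjusted p was 0.0134, and adjusted p = 0.291 with an estimated correlation. Hist1h2bb stood at 10.1 ± 2.81 FPKM, from 43, 27 and 54 reads, against 0 reads in the 3 NP@M libraries. That was at least 52.2-fold higher in the authors' scaling. Hist1h2ae rose from 0.155 ± 0.228 to 9.09 ± 1.58 FPKM. The NP@M mean of Hist1h2ae was 0.0240 FPKM without NP@M replicate 1. Of the 50-base words of these genes, 40.1% and 43.2% occur in other genes. With a trend on gene length removed, the histone call was lost (adjusted p = 0.784). For the histone RNAs too, a difference in capture was not tested.

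Of 37 genes of G2/M and mitosis, 7 rose and 29 fell in NP-D@M vs NP@M (7 and 29 adjusted over the list alone, 0 and 35 scaled to the reads in the table). Their median lay at -0.79 relative to all genes (camera adjusted p = 0.00486, and adjusted p = 0.198 with an estimated correlation). Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189, GRCm38), the topoisomerase gene of chromosome separation, fell from 38.0 ± 2.26 to 2.41 ± 0.665 FPKM (n = 3). The mitotic kinase gene Aurka fell from 22.5 ± 1.71 to 0.957 ± 0.625 FPKM. All 5 tested CDK inhibitor protein genes fell (5 adjusted over the list alone), with Cdkn2d down from 16.3 ± 0.463 to 0.868 ± 0.321 FPKM. Camera gave them an adjusted p of 0.0483, and adjusted p = 0.212 with an estimated correlation. That list call ended without NP@M replicate 2, NP-D@M replicate 1 or NP-D@M replicate 2 (adjusted p up to 0.062).

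The other lists were not called by camera in this comparison, and their counts were the same when adjusted over the list alone. With a trend on gene length removed, short-lived and immediate early transcripts were called lower (adjusted p = 0.0137), but not without that removal (adjusted p = 0.115, and adjusted p = 0.615 with an estimated correlation). Of 27 CDKs and cyclins, 7 rose and 19 fell. Of 34 genes of DNA replication and S phase, 19 rose and 14 fell, which turned to 3 and 28 scaled to the reads in the table and 11 and 16 with quantile normalization. Of 27 p53 targets 7 rose and 16 fell, and of 32 short-lived and immediate early transcripts 7 rose and 19 fell. Of 8 anti-apoptotic genes 2 rose and 6 fell, and of 14 pro-apoptotic genes 4 rose and 8 fell. Of 24 interferon-stimulated genes 9 rose and 14 fell, and of 14 checkpoint ligands and immune evasion genes 5 rose and 9 fell. Of 15 NF-kB pathway and target genes 2 rose and 11 fell, and of 12 genes of cytosolic DNA and RNA sensing 2 rose and 10 fell. Of 10 chemokines and cytokines 6 rose and 2 fell, which turned to 4 and 5 scaled to the reads in the table. Rises and falls were 13 and 7 of 21 in glycolysis and hypoxia, which turned to 7 and 12 scaled to the reads in the table and 7 and 10 with quantile normalization. They were 16 and 8 of 25 in the NRF2 and oxidative stress response (7 and 12, and 10 and 10, under these scalings). They were 15 and 14 of 29 in the unfolded protein response (6 and 19, and 10 and 17) and 11 and 10 of 21 in cholesterol biosynthesis (1 and 16, and 6 and 12). Heat shock proteins gave 8 rises and 9 falls of 18, which became 1 and 12 scaled to the reads in the table and 4 and 13 with quantile normalization. Extracellular matrix and mesenchymal genes gave 8 and 9 of 20, which became 3 and 15 scaled to the reads in the table. DNA damage repair gave 7 and 15 of 27, which became 10 and 10 with quantile normalization, and RNA polymerase II transcription and elongation gave 9 and 17 of 27.

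**Figure D3:**
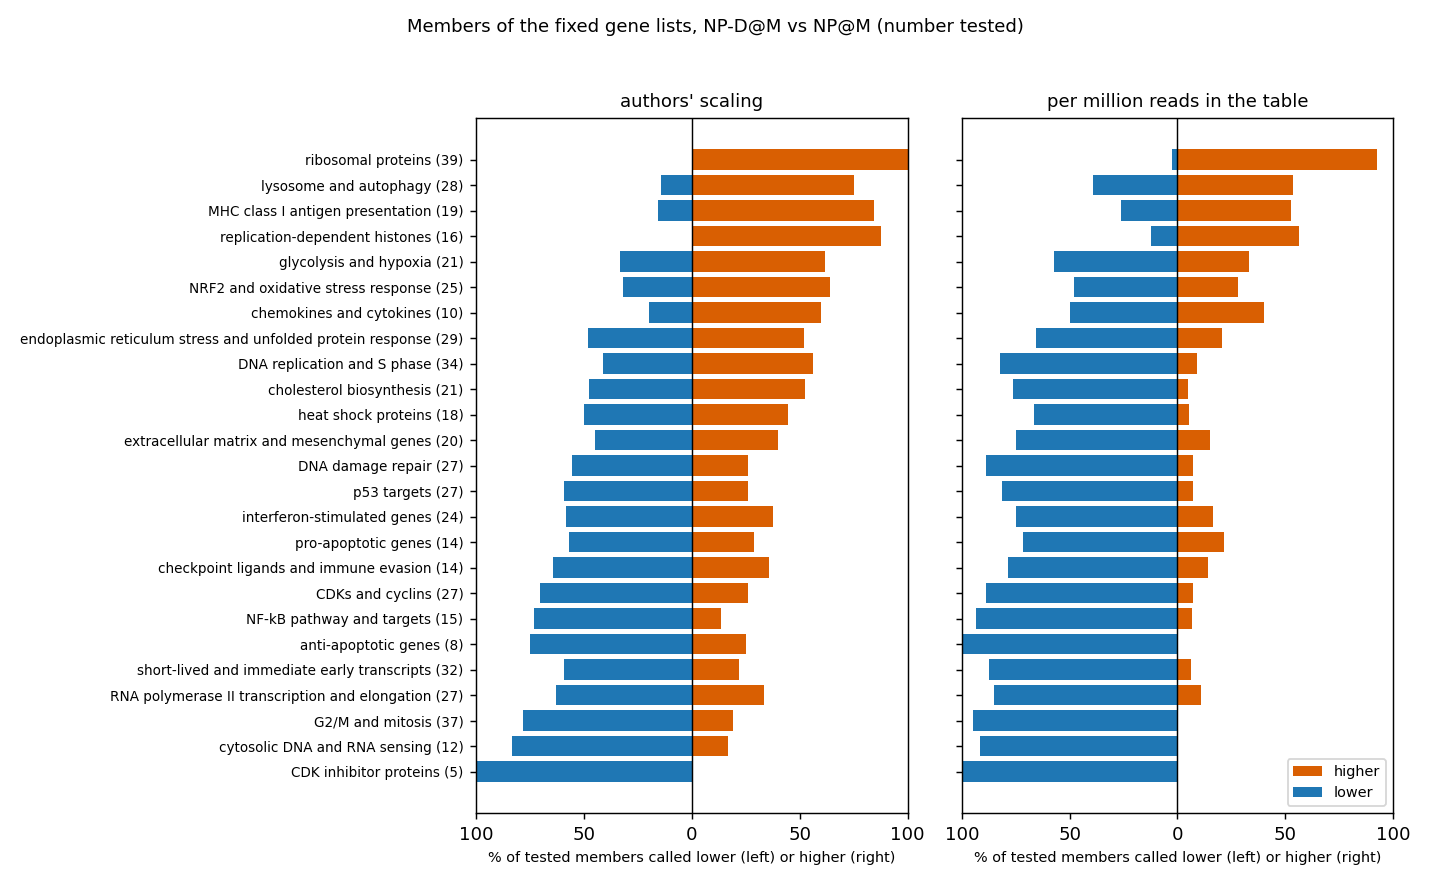
Share of the tested members (%) called lower, to the left, and higher, to the right, for the 25 tested gene lists in NP-D@M vs NP@M, in the authors' scaling and scaled to the reads in the table. Ribosomal proteins had 39 of 39 members higher in the authors' scaling and 36 higher and 1 lower scaled to the reads in the table (13 higher and 14 lower with quantile normalization), and CDK inhibitor proteins had 5 of 5 members lower in both panels.

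Markers of other cell types went in both directions with D, and the examples here were singled out after their values were seen. The colon epithelium marker Krt20 rose from 8.67 ± 0.753 to 78.0 ± 5.81 FPKM in NP-D@M vs NP@M (n = 3), with 1 of 2 tested markers called higher and 0 lower (1 and 1 scaled to the reads in the table). All 4 tested fibroblast and stromal markers fell, among them the collagen gene Col1a2 from 54.3 ± 1.52 to 9.25 ± 1.61 FPKM. Of 4 tested myeloid markers 3 rose and 1 fell (1 and 1 scaled to the reads in the table), and the lysosomal glycoprotein gene Cd68 rose from 2.38 ± 0.368 to 12.5 ± 4.05 FPKM. The platelet marker Ppbp, the only red blood cell and platelet marker tested, rose from 0.903 ± 0.426 to 6.02 ± 3.44 FPKM but was not called when scaled to the reads in the table. Of 20 retina markers, 20 T and NK cell markers and 15 hepatocyte markers, 3, 1 and 0 were in the table and 0 passed the filter.

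In all, limma called 9037 of 10101 genes in NP-D@M vs NP@M, 4222 higher and 4815 lower, of which 5908 had a log2 change of at least 1 in size. The share higher among the calls was 46.7%, and 19.9% scaled to the reads in the table. The groups did not overlap in 8820 genes (87.3%), where the mean over splits is 10%.

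The comparison of NP-D@MP with NP-D@M sets the treatments with D in their names against each other. Limma called 4 genes higher and 1 lower with Benjamini-Hochberg adjustment, and these 5 are named after their values were seen. The pseudogene Gm11461 (ENSMUSG00000083264, chromosome 2, 165925266 to 165925841, GRCm38) stood at 1.97 ± 0.489 FPKM against 0 (n = 3, limma adjusted p = 0.000165). It had 7, 6 and 4 reads with NP-D@MP. The pseudogene Gm4322 (ENSMUSG00000100690, chromosome 1, 150268926 to 150269261) stood at 1.62 ± 0.455 FPKM against 0 (limma adjusted p = 0.00435). It had 4, 3 and 5 reads with NP-D@MP, and 69.3% of its 50-base words occur in other genes. The small nuclear RNA Gm22818 (ENSMUSG00000088071, chromosome 15, 86212554 to 86212657) fell from 277 ± 17.9 to 168 ± 1.42 FPKM (limma adjusted p = 0.00435). Mcat (ENSMUSG00000048755, chromosome 15, 83546797 to 83563787), a gene of mitochondrial fatty acid synthesis that overlaps Tspo, rose from 0.0660 ± 0.114 to 1.06 ± 0.143 FPKM (limma adjusted p = 0.0189). Borcs5 (ENSMUSG00000042992, chromosome 6, 134639510 to 134711187), a gene of lysosome positioning, rose from 0.0324 ± 0.0561 to 0.718 ± 0.0940 FPKM (limma adjusted p = 0.0463). Without NP-D@M replicate 3 the NP-D@M means of Mcat and Borcs5 were 0. Limma voom called 0 genes, these 5 having an adjusted p of 0.233 each. A fit on the 6 libraries alone also called 0, and 2 of the 5 were called when scaled to the reads in the table. In this comparison 1713 genes had an unadjusted p under 0.05 in limma. None of the 13 fixed genes was called. Cd274 stood at 0.463 ± 0.222 against 0.112 ± 0.194 FPKM (limma adjusted p = 0.26) and Mcl1 at 13.4 ± 1.78 against 9.79 ± 3.31 FPKM (limma adjusted p = 0.263). Short-lived and immediate early transcripts stood higher than other genes by a median of 0.21 (camera adjusted p = 0.00148, and adjusted p = 0.77 with an estimated correlation), with 0 of 32 members called over all genes and 1 higher when adjusted over the list alone. Ribosomal proteins stood higher by a median of 0.15 (camera adjusted p = 0.0218, and adjusted p = 0.77 with an estimated correlation), with 0 of 39 members called over all genes or adjusted over the list alone. Without NP-D@M replicate 2 these list calls also ended (adjusted p = 0.095 and 0.282), as did that of ribosomal proteins without NP-D@MP replicate 1 and with a trend on gene length removed (adjusted p = 0.147). Here too, neither list was tested with a GC trend removed.

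The count of genes in this comparison depended on NP-D@M replicate 3. Without it, limma called 1259 genes, 969 higher and 290 lower with NP-D@MP. Over all genes that was 969 of 10101 higher. The lists with the most calls, picked after the values were seen, were ribosomal proteins (14 of 39 higher, 0 lower), short-lived and immediate early transcripts (9 of 32 higher, 0 lower) and histones (6 of 16 higher, 1 lower). Each of the other gene lists had at most 4 higher and 2 lower, among them G2/M and mitosis (4 higher and 2 lower of 37), the unfolded protein response (4 and 2 of 29), chemokines and cytokines (0 and 2 of 10) and CDKs and cyclins (0 and 1 of 27). These counts rest on NP-D@M replicates 1 and 2, which had 2199 and 2174 genes at 0 and mitochondrial shares of 13.2% and 14.4%, against 1104 to 1211 genes and 7.41% to 10.2% in NP-D@MP. Their slopes on GC content were 0.33 and 0.32 per 10% on the log2 scale, against 0.52 to 0.61. Mcl1 was then higher by 0.68 on the log2 scale (limma adjusted p = 0.014) and Cd274 higher by 0.54 (limma adjusted p = 0.0485). Ccl5 was lower, at a log2 change of -0.94 (limma adjusted p = 0.03). Without NP-D@M replicate 1, limma called 14 genes. With all libraries, the groups did not overlap in 1432 genes (14.2%), where the mean over splits is 10% and a single split can lie above it.

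The comparison of NP-D@M with PBS sets that treatment against the PBS cells. Cdk1 fell from 17.6 ± 0.582 to 1.59 ± 0.515 FPKM (n = 3, log2 change -2.86, SE 0.139, limma Benjamini-Hochberg adjusted p = 3.28e-09), Cdk2 from 4.59 ± 0.350 to 1.47 ± 0.126 FPKM and Cdkn1a from 45.6 ± 2.96 to 9.41 ± 0.685 FPKM. Cdk5 rose from 6.56 ± 0.859 to 71.1 ± 10.4 FPKM and Cxcl10 from 0.288 ± 0.0582 to 3.74 ± 0.421 FPKM. Cxcl10 had 16, 24 and 18 reads with PBS and 65, 69 and 66 with NP-D@M. The kinase gene Sgk1 fell from 19.3 ± 0.350 to 1.13 ± 0.0986 FPKM. Rnu12, with 0 reads in the 3 PBS libraries, stood at 303 ± 89.8 FPKM, from 433, 220 and 456 reads. That was at least 455-fold higher in the authors' scaling. Rps29 rose from 67.2 ± 5.45 to 2013 ± 267 FPKM, with 26.5% of its 50-base words in other genes. Prl2c2 rose from 0.246 ± 0.0907 to 40.4 ± 10.2 FPKM, a level that is uncertain because 89.5% of its 50-base words occur in other genes. The call of Mdm2 (-0.25, limma adjusted p = 0.0354) ended without PBS replicate 1, PBS replicate 3 or NP-D@M replicate 2 (adjusted p of 0.113 to 0.121). It also ended with a GC trend removed (log2 change -0.083, adjusted p = 0.407) and in a fit on the 6 libraries alone (log2 change -0.25, adjusted p = 0.0943).

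By lists in NP-D@M vs PBS, 39 of 39 ribosomal proteins rose (39 adjusted over the list alone), with 35 higher and 0 lower scaled to the reads in the table but 10 higher and 19 lower with quantile normalization. Their camera adjusted p was 2.95e-12, and adjusted p = 0.242 with an estimated correlation. Of 28 lysosome and autophagy genes 21 rose and 3 fell (21 and 3 adjusted over the list alone, 15 and 10 scaled to the reads in the table), Ctsb among them. Camera gave them an adjusted p of 0.000135, and adjusted p = 0.195 with an estimated correlation. Of 19 MHC class I genes 16 rose and 3 fell (16 and 3 adjusted over the list alone, 10 and 5 scaled to the reads in the table), Calr among them. Their camera adjusted p was 0.00204, and adjusted p = 0.195 with an estimated correlation. Of 16 histone genes 14 rose and 0 fell (14 and 0 adjusted over the list alone, 11 and 1 scaled to the reads in the table), a call that was lost with a trend on gene length removed (adjusted p = 0.612). Camera gave them an adjusted p of 0.00761, and adjusted p = 0.247 with an estimated correlation. Of 37 genes of G2/M and mitosis 7 rose and 29 fell (7 and 29 adjusted over the list alone, 0 and 35 scaled to the reads in the table), Top2a and Aurka among them. Their camera adjusted p was 0.00571, and adjusted p = 0.195 with an estimated correlation. All 5 CDK inhibitor protein genes fell (5 adjusted over the list alone). Camera gave them an adjusted p of 0.0349, and adjusted p = 0.233 with an estimated correlation. Of 32 short-lived and immediate early transcripts 6 rose and 21 fell (6 and 21 adjusted over the list alone), Fosb among them. Their camera adjusted p was 0.0349, and adjusted p = 0.548 with an estimated correlation. In all, limma called 4199 genes higher and 4795 lower, 46.7% higher among 8994 calls and 18.9% scaled to the reads in the table. The groups did not overlap in 8857 genes (87.7%), where the mean over splits is 10%.

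The comparison of NP-D@MP with PBS sets the remaining treatment against the same PBS cells. Cdk1 fell from 17.6 ± 0.582 to 1.23 ± 0.292 FPKM (n = 3, log2 change -3.07, SE 0.139, limma Benjamini-Hochberg adjusted p = 1.69e-09). Mcl1 fell from 58.9 ± 2.49 to 13.4 ± 1.78 FPKM and Trib3 from 69.0 ± 8.98 to 0.718 ± 0.185 FPKM. Pnrc2, a gene of RNA decay, fell from 25.5 ± 2.88 to 0.777 ± 0.674 FPKM, and the small GTPase gene Arf6 from 41.8 ± 1.14 to 2.33 ± 0.777 FPKM. B2m rose from 577 ± 4.76 to 5393 ± 282 FPKM, a direction that turned to -0.075 with quantile normalization, and H2-K1 rose from 15.6 ± 0.816 to 176 ± 42.5 FPKM. Cd274 stood at 0.463 ± 0.222 against 1.03 ± 0.0397 FPKM (log2 change -0.48, limma adjusted p = 0.013), from 6, 14 and 17 reads against 119, 110 and 105. Its log2 change turned to 0.051 with quantile normalization, while its call was kept when scaled to the reads in the table. It was no longer called without NP-D@MP replicate 1 (log2 change -0.36, adjusted p = 0.0597), with a GC trend removed (log2 change -0.21, adjusted p = 0.23), with a pseudocount of 0.1 (log2 change -1.09, adjusted p = 0.0785) or by limma voom (log2 change -1.23, adjusted p = 0.0597). The mitochondrial gene mt-Co3 stood at 1254 ± 1409 against 17.4 ± 0.380 FPKM, with 16102 reads in NP-D@MP replicate 3 and 2905 and 2302 in the other NP-D@MP libraries, whose mean was 441 FPKM. Its level is uncertain, since 99.9% of its 50-base words occur in other genes. Ccl5, called at a log2 change of 1.04, had an adjusted p of 0.153 scaled to the reads in the table. The call of Mdm2 (-0.23, limma adjusted p = 0.043) ended without PBS replicate 1, PBS replicate 3 or any of the 3 NP-D@MP libraries (adjusted p of 0.0625 to 0.141). It also ended with a GC trend removed (log2 change -0.016, adjusted p = 0.871), with a pseudocount of 0.1 (log2 change -0.25, adjusted p = 0.0526) and in a fit on the 6 libraries alone (log2 change -0.23, adjusted p = 0.0536).

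By lists in NP-D@MP vs PBS, 39 of 39 ribosomal proteins rose (39 adjusted over the list alone, camera adjusted p = 4.76e-12, and adjusted p = 0.187 with an estimated correlation), with 35 higher and 1 lower scaled to the reads in the table but 13 higher and 16 lower with quantile normalization. Of 28 lysosome and autophagy genes 21 rose and 3 fell (21 and 3 adjusted over the list alone, 15 and 10 scaled to the reads in the table, camera adjusted p = 0.000137, and adjusted p = 0.187 with an estimated correlation), Psap among them. Of 19 MHC class I genes 16 rose and 2 fell (16 and 2 adjusted over the list alone, 10 and 5 scaled to the reads in the table, camera adjusted p = 0.00188, and adjusted p = 0.187 with an estimated correlation), Psme1 among them. All 16 tested histone genes rose (16 adjusted over the list alone, camera adjusted p = 0.00325, and adjusted p = 0.187 with an estimated correlation), with 14 higher and 1 lower scaled to the reads in the table. With a trend on gene length removed the histone call was lost (adjusted p = 0.507). Short-lived and immediate early transcripts were then called lower (adjusted p = 0.0164). Without that removal they were not (camera adjusted p = 0.132, and adjusted p = 0.675 with an estimated correlation). Without a filter on low values, genes of cytosolic DNA and RNA sensing were called lower (adjusted p = 0.0476), though not with the filter (adjusted p = 0.0864, and adjusted p = 0.187 with an estimated correlation). Of 37 genes of G2/M and mitosis 8 rose and 29 fell (8 and 29 adjusted over the list alone, 0 and 36 scaled to the reads in the table, camera adjusted p = 0.0039, and adjusted p = 0.187 with an estimated correlation), Top2a and Aurka among them. All 5 CDK inhibitor protein genes fell (5 adjusted over the list alone, camera adjusted p = 0.0492, and adjusted p = 0.187 with an estimated correlation), and this call ended without PBS replicate 2 or NP-D@MP replicate 2 (adjusted p up to 0.0534). In all, limma called 4367 genes higher and 4777 lower, 47.8% higher among 9144 calls and 19.9% scaled to the reads in the table. The groups did not overlap in 9397 genes (93.0%), where the mean over splits is 10%.

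The responses to NP-D@M and NP-D@MP were compared across the 10101 genes, which are not independent replicates. Cdk1, Top2a and Trib3 were lower and Rplp0, Ctsb and Calr higher both in NP-D@M vs NP@M and in NP-D@MP vs PBS, which share no libraries. The log2 changes of this pair correlated at r = 0.983 with a covariance of 2.71 and had the same sign in 97.8% of genes. They shared 4044 genes called higher, where independent lists would share 1825, and 4588 called lower, where independent lists would share 2277. Against the same PBS libraries the changes correlated at r = 0.984 with a covariance of 2.65, where simulated unchanged groups (100 draws) gave r = 0.50 and a covariance of 0.0176.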

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

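Scaling to the reads in the table, limma voom, removal of a GC trend and removal of a length trend were chosen after seeing the data, while the other settings were fixed before the data were examined. No paired analysis was made, because the labels give no pairing of libraries across groups, which does not exclude one. For genes changed in NP@M vs PBS, 1 in the analysis as reported, quantile normalization gave 7, no filter 4, a pseudocount of 0.1 gave 2, a fit on the 6 libraries alone 2, a mean of at least 5 FPKM 0 and limma voom 0, and leaving out a library gave 1 to 2. For NP-D@MP vs NP-D@M, 5 as reported, no filter gave 21, a pseudocount of 0.1 gave 26, 2 were left when scaled to the reads in the table, a log2 change of at least 1 gave 2, an adjusted p under 0.01 gave 3, a mean of at least 5 FPKM 1, and limma voom and a fit on the 6 libraries alone 0; leaving out a library gave 4 to 1259, the highest without NP-D@M replicate 3. The stricter thresholds lower a count by construction, and otherwise the cause was not tested. The 9037, 8994 and 9144 genes of NP-D@M vs NP@M, NP-D@M vs PBS and NP-D@MP vs PBS became 4574, 4562 and 4584 with a mean of at least 5 FPKM, which tested 4944 genes, and 5908, 5802 and 5977 with a log2 change of at least 1. Leaving out a library changed them to 8707 to 8991, 8676 to 8941 and 8828 to 8925.

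With an estimated inter-gene correlation, 0 gene lists were called in each of the 5 comparisons, in place of 2 in NP@M vs PBS, 6 in NP-D@M vs NP@M, 2 in NP-D@MP vs NP-D@M, 7 in NP-D@M vs PBS and 6 in NP-D@MP vs PBS. With the length trend removed, 1 list was called in NP@M vs PBS and 1 in NP-D@MP vs NP-D@M. Leaving out a library gave 1 to 2, 5 to 6, 0 to 2, 7 to 7 and 5 to 6 lists in that order. The correlation of 0.983 between the responses was 0.980 by Spearman and 0.990 over genes with a mean of at least 5 FPKM.

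For single genes, with quantile normalization B2m turned to -0.15 in NP-D@M vs NP@M and -0.075 in NP-D@MP vs PBS, and Cd274 to 0.051 in NP-D@MP vs PBS; the cause was not tested. Of the other values of single genes under alternatives, 2305 kept their direction and side of the threshold, 21 lost the call (13 of Mdm2, 6 of Cd274, 1 of B2m and 1 of Ccl5) and 3 gained it (Cd274, Mcl1 and Ccl5, without NP-D@M replicate 3). In data simulated with a dispersion of 0.01, 58.2% of genes changed 1.5-fold were called in NP-D@MP vs NP-D@M. The simulation did not vary the depth.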

Other observations

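The tests chosen only after the result was seen were those of a wrong label and of the mitochondrial share for NP-D@M replicate 3, the test on genes chosen over all 6 libraries with D, the test of GC content for NP@M vs PBS, all splits of the libraries, and the families of genes. The genes for the test of reads at 0 were chosen again, over all 6 libraries, after the first value was seen, and both values are given. The bars for a wrong label, a small share of untreated RNA, fewer distinct molecules and scaling of the libraries were made stricter after their values were seen, which left them open.

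Of 29 small nuclear RNAs, 26 rose and 0 fell in NP-D@M vs NP@M, with 26 higher both when scaled to the reads in the table and with quantile normalization. Whether their capture in the libraries differed with D was not tested. Of 78 respiratory chain genes of the nucleus 77 rose and 0 fell (64 and 7 scaled to the reads in the table, 64 and 9 with quantile normalization). Of 190 zinc finger genes 15 rose and 157 fell (2 and 185, and 20 and 102, under these scalings). Of 742 pseudogenes 563 rose and 68 fell (349 and 134, and 560 and 71). Of 33 proteasome genes 25 rose and 5 fell, which turned to 8 and 19 scaled to the reads in the table and 14 and 16 with quantile normalization, and of 79 mitochondrial ribosomal proteins 45 rose and 24 fell, which turned to 18 and 51 scaled to the reads in the table. Of 26 small nucleolar RNAs 10 rose and 7 fell, which turned to 7 and 9 scaled to the reads in the table. Of 306 long noncoding RNAs 245 were called, 144 of them higher, and with quantile normalization 164 rose and 62 fell, but 54 rose and 165 fell when scaled to the reads in the table. Of 13 messenger RNAs encoded in the mitochondrion 12 rose and 0 fell (12 and 0 scaled to the reads in the table, 6 and 2 with quantile normalization). Of 30 aminoacyl-tRNA synthetases 16 rose and 11 fell, which turned to 5 and 22 scaled to the reads in the table and 10 and 13 with quantile normalization. Short members of these classes could pass the filter on fewer reads with D than without it. The counts were not repeated under another filter.

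With D, short genes were higher and long genes lower among the tested genes, by the gene length in the deposited table. That length can exceed the longest annotated transcript (9013 against 5221 bases for Top2a). In NP-D@M vs NP@M the 10% of genes with the shortest length had a median log2 change of 1.70. The 10% with the longest had -0.64, a gap of 2.34. These genes had passed the filter of at least 1 FPKM in at least 3 libraries in the authors' scaling. A read was worth more FPKM with D, so short genes could pass on fewer reads there. How much of the gap comes from this filter was not tested. GC content and the ribosomal protein, mitochondrial and pseudogene entries were argued against as the whole cause, since 89.4% of the gap was kept with a GC trend removed and 83.6% without those entries. At equal gene length in the table, the correlation across genes with genomic span was -0.0566 (95% interval -0.0745 to -0.0379). Over protein-coding genes it was -0.0273 (-0.0460 to -0.00311) and, in NP-D@M vs PBS, -0.00322 (-0.0206 to 0.0159). The length of the transcription unit therefore stays open. The 95% intervals here come from 200 draws of genes, which are not independent replicates, and leave out the spread between libraries. At equal span the correlation with that gene length was -0.180 (95% interval -0.199 to -0.163). It may come from the state of the RNA, the library preparation or the treatment. These cannot be told apart, because every library with D had the treatment.

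NP-D@M replicate 3 lay closer to the NP-D@MP libraries (r of 0.990 or higher) than to NP-D@M replicates 1 and 2 (0.978 to 0.980), and GC content was argued against, since 86.4% of the excess correlation was kept with its trend removed. A wrong label stays open, because replicates 1 and 2 correlated at only 0.976 with each other, no better than with NP-D@MP (0.975 to 0.981). A small share of RNA from untreated cells is argued against for the mitochondrial share, where 13.4% would be seen at the largest share allowed and 9.06% was seen, beyond the difference of 1.23 between replicates 1 and 2. For the 17 genes at 0 in replicates 1 and 2 it stays open: 0.730% was needed and 3.86% allowed (ratio 0.189), but 3.70% and 3.69% were allowed in replicates 1 and 2 as well, and these genes stood at 1.05% to 1.41% of control in NP-D@MP. Fewer distinct RNA molecules in replicates 1 and 2 also stays open: of 8446 genes chosen over NP-D@MP, 55 and 53 were at 0 there (mean 54) and of 8473 chosen over all 6 libraries 37 and 30 (mean 33.5), against 0 in replicate 3, so the divisor was set to 1, with 6 and 2 at 0 in both replicates where independence gives 0.345 and 0.131, and both choices favour genes present in libraries that replicate 3 resembled.

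In NP@M vs PBS, 28.4% of genes had groups that did not overlap, where the mean over splits is 10%. The share was not computed for the other splits, so how far a single split can lie above 10% is not known. Scaling of the libraries stays open: 28.9% did not overlap when scaled to the reads in the table, and the genes with an unadjusted p under 0.05 went from 1092 to 1866, but the median log2 change moved by only 0.0052, so a shift between the groups was hardly tested. With a GC trend removed 20.2% did not overlap and these genes went from 1092 to 526, so GC content may account for part of the pattern. The 10% of genes with the lowest GC content had a median log2 change of 0.21 and the 10% with the highest -0.21. An effect of NP@M stays open and was not tested apart from the libraries.

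For each comparison the 6 libraries make 10 splits, too few for a share under 0.05, and each split was fitted on those libraries alone. The real split gave 2 genes in NP@M vs PBS, 8683 in NP-D@M vs NP@M, 8697 in NP-D@M vs PBS and 9384 in NP-D@MP vs PBS, and the highest other split gave 0, so 1 split of 10 gave as many. Where only 1 group had D, every other split put libraries with and without D on both sides. That widens the spread within a side, so the 0 there carries no information. In NP-D@MP vs NP-D@M the real split and the highest other split gave 0, so 10 of 10 gave as many.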
